A study of Mus musculus with 11 samples.

How the data were processed

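RNA was measured in 11 samples of mouse kidney cells that the labels call primary kidney fibroblasts. The cells came from C57BL/6 kidneys after tissue digestion and were enriched in DMEM with serum, per the labels' protocols. Of these samples, 3 came from control kidneys, 4 from kidneys 3 days after unilateral ureteral obstruction (UUO, surgery that blocks the ureter of one kidney and is used to induce renal fibrosis) and 4 from kidneys 7 days after it. Groups and replicate numbers were taken from the sample titles. The labels do not say that the replicates of a group are separate animals, so the p-values measure the spread between these samples, which may be technical in part. Total RNA was extracted with Trizol and made into stranded libraries for sequencing on an Illumina NovaSeq, per the labels' protocols.

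The authors deposited a table of FPKM values per gene and one per transcript, per the file headers. FPKM is a fragment number scaled to transcript length and to the mapped fragments of the library. The submitters' processing notes name cutadapt, HISAT2, StringTie and the GRCm38 genome, without versions, roles or order. The annotation release and the exact counting settings are not given in the sources used here. The gene table lists 13985 genes, all typed as protein coding, and the one per transcript holds 26807 transcripts of 13936 genes. Every listed gene has a mean of at least 0.5 FPKM in one or more groups (the lowest such mean is 0.5002), so genes below that level in all groups were not analysed here. In all, 17 symbols belong to 2 gene identifiers each, and 1 line of each table held no values. In 22 genes, such as Mup20, a library stands at exactly 0 and another of its group at 10 FPKM or more. Whether a 0 means absence was not tested. The tables hold no counts, and low values did not fall on clean multiples of a single-read step, so the depth per sample is unknown and no counting interval is given. Genes with near-identical copies, such as the hemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, the heat shock genes Hspa1a and Hspa1b and the major urinary protein genes, share reads, and their single values are uncertain. Coordinates are those of the deposited table.

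Tests were run on log2(FPKM + 1) of the FPKM values as deposited, without further scaling, in the 13428 genes with a mean of at least 0.5 FPKM over the 11 samples. The other 557 genes fell under that minimum. Fold changes are on this scale and understate the change of low genes. One linear model with the 3 groups as levels was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, so that all samples share one estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, within each of 3 comparisons: day 3 with control, day 7 with control, and day 7 with day 3. The last of these is also the test of whether the effects of the 2 times differ. Adjusted p-values for genes are from limma throughout. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

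Lists of genes were fixed before the data were examined, as were the tests, the rule for named genes and all alternatives but those said below to have been added later. The 39 lists cover collagens, other matrix proteins, collagen processing, matrix proteases and inhibitors, contractile and myofibroblast genes, the TGF-beta pathway, stromal and pericyte identity, mitosis, DNA replication, replication-dependent histones, the interferon response, inflammatory cytokines and NF-kB targets, complement, glycolysis and hypoxia, oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis, endoplasmic reticulum stress, p53 and senescence, the Wnt pathway, YAP and SRF targets, oxidative stress defence, the insulin-like growth factor axis, immediate early genes, cytosolic ribosomal proteins, the mitochondrial genome and sex-linked transcripts. A further 12 lists hold markers of other cells: proximal tubule, distal nephron and collecting duct, general and injured epithelium, macrophage, neutrophil, lymphocyte, endothelium, podocyte, mesothelium, glia, adipocyte and red blood cell. Each list was tested against all other genes with camera from limma, with a preset correlation of 0.01 between its genes, and again with the correlation estimated from the residuals. The fry test of limma was run beside it. It asks whether the genes of a list move, on balance, in one direction, and does not compare the list with other genes. For each list the members called over all genes tested were counted, and also those called when adjusted over the list alone. The latter count is given where it differs.

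Genes are named by a fixed rule. The first part takes, per comparison with control, the 8 largest rises and 8 largest falls among called genes with a group mean of at least 5 FPKM, no overlap between the libraries of both groups and no provisional symbol. For the comparison between the days it takes 5 of each. The second part is a panel of 10 genes of myofibroblasts and matrix. The third part takes the members with the largest changes of each list described. Some genes that the rule takes are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

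Whether replicate numbers pair the samples was checked from the correlation across genes of each sample's deviations from its group mean. For day 7 with control the 3 same-numbered pairs correlated at 0.168, 0.428 and 0.166, each above 0.1. Each day 7 sample of these pairs correlated best with the control of its own number. The best day 7 match of each control was not looked up, and day 7 replicate 4 has no same-numbered control. These numbers were therefore treated as pairing the samples, although no label says so, and a fit of all 11 samples with the replicate number as a block was compared. For the other comparisons not every pair passed 0.1. The fits were tested on simulated data with known changes in 200 of 13428 genes. For day 3 with control, 56.7% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 98.5% of those changed 4-fold were called, with 8 unchanged genes called. For day 7 with control these shares were 43.3%, 80.6% and 97%, with 5 unchanged genes called, and for day 7 with day 3 they were 55.2%, 86.6% and 97%, with 4. A planted list of 20 genes was called by camera with either correlation and by fry in each comparison, and fry also called 2 unchanged lists for day 7 with control. The simulated genes were drawn independently, whereas the genes of real lists correlate, at an estimated 0.781 for the collagens. The simulation therefore cannot show how often camera with the preset of 0.01 calls an unchanged list of correlated genes.

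Alternatives covered the pseudocount (0.1 and 0.5), the minimum mean (none, and 2 FPKM), median centring, quantile normalization, rescaling each sample to the same sum as TPM does, the variance model (no trend, robust), sample weights, the replicate block, gene values summed from the transcript table, fits of only 2 groups, thresholds of adjusted p 0.01 and of 2-fold change, and leaving out each library in turn. Leaving out the mitochondrial genome before rescaling was added after the data had been seen. So were 24 liver genes, counts of genes far above every other library and list counts under each scaling. Rescaling to TPM also lowers the weight of the pseudocount. Scaling matters here because the FPKM sums differed between groups. The median log2 fold change of all genes tested was 0.26 at day 3 and 0.28 at day 7 as deposited. It was −0.07 and −0.03 after median centring, −0.01 and 0.01 after quantile normalization, and 0.69 and 0.76 after rescaling to TPM. Changes of lists are therefore given relative to the median of all genes in the same comparison.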

Results

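To follow the transcriptome of kidney fibroblast preparations after ureteral obstruction, RNA-seq profiles of cells from control mouse kidneys (n = 3) were compared with those from obstructed kidneys 3 days (n = 4) and 7 days (n = 4) after surgery. Expression is given as FPKM, mean ± SD, with the n above for each group. The depth per sample is unknown because the values are FPKM.

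In the control libraries, 31.5% ± 5.47 of the summed FPKM came from the 13 protein genes of the mitochondrial genome, compared with 6.81% ± 0.568 at day 3 and 5.94% ± 1.65 at day 7. The summed FPKM was 369813 in control, 275068 at day 3 and 265154 at day 7 on average. Without the mitochondrial genes it was 253497, 256360 and 249418. The first principal component held 76% of the variance and parted control from UUO libraries. Libraries of the same group correlated at 0.965 to 0.992 across genes, control with day 3 at 0.791 to 0.864, control with day 7 at 0.75 to 0.768 and day 3 with day 7 at 0.933 to 0.965. Genes are not independent replicates in these correlations. No libraries held identical values.

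**Figure D1:**
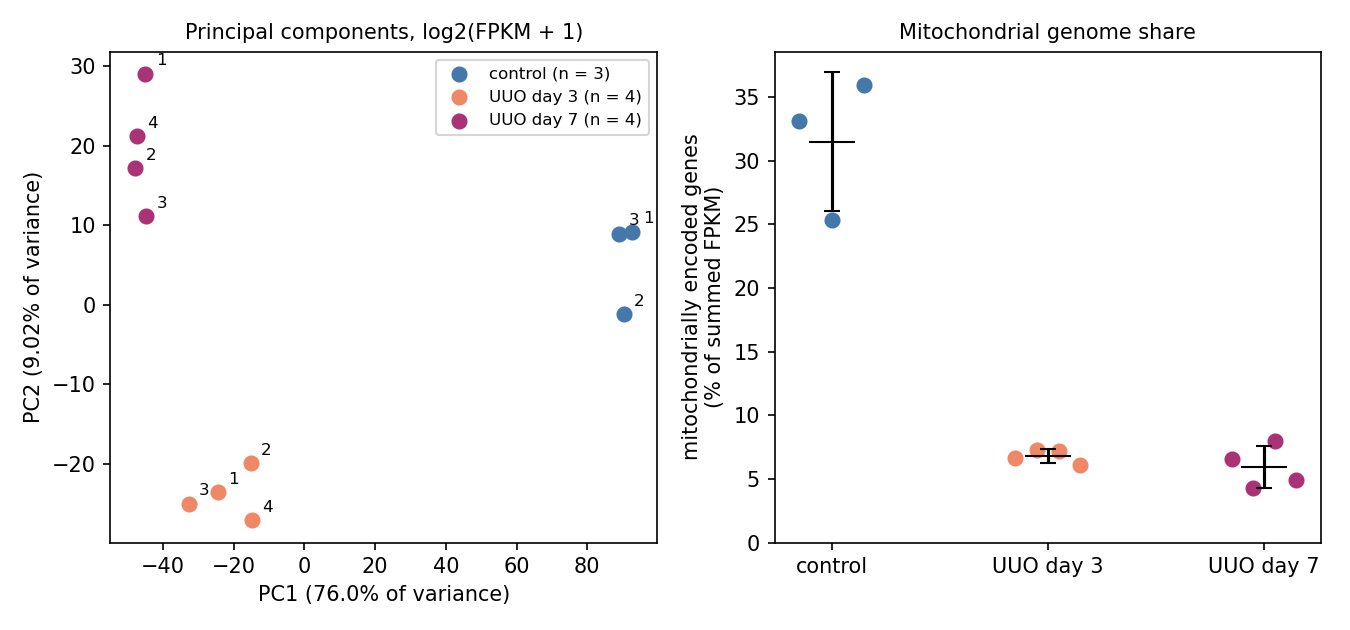
Left, the first and second principal components of log2(FPKM + 1), one point per library, holding 76% and 9.02% of the variance. Right, the percentage of summed FPKM from mitochondrially encoded genes in each library, with the group mean and SD, from 25.4 to 35.9% in the 3 control libraries and lower in every UUO library.

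Transcripts of other kidney cells were measured in these preparations. All 20 proximal tubule markers stood at 5 FPKM or more in control, led by Kap, the kidney androgen-regulated protein of the proximal tubule, at 11100 FPKM. The list made up 6.28% of the nuclear FPKM in control, 0.672% at day 3 and 0.299% at day 7. Distal nephron and collecting duct markers, led by Umod (uromodulin), fell from 1.06% to 0.379% and 0.277%. Macrophage markers went from 0.633% to 3.42% and 3.63%, with Cd74 (the MHC class II invariant chain) at 549, 1500 and 1710 FPKM. Red blood cell markers went from 1.59% to 0.0579% and 0.0367%. Collagens made up 0.0587%, 0.433% and 1.44% of the nuclear FPKM, and stromal and pericyte markers 0.0976%, 0.131% and 0.204%. The stromal and pericyte markers summed to 247, 335 and 510 FPKM, of which Ly6a alone held 188, 213 and 169 FPKM. Their share therefore understates the rise of the other members. In addition, 39 genes stood at least 10 times higher in day 3 replicate 1 than in any other library, among them Alb (albumin), with 261 FPKM against at most 3.04 elsewhere. None of the 38 of these that were tested was called by limma at day 3 or between the days, and 0 had an unadjusted p under 0.05. A group test can hardly call genes chosen for a single extreme library, so this does not show that other calls are free of its influence.

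**Figure D2:**
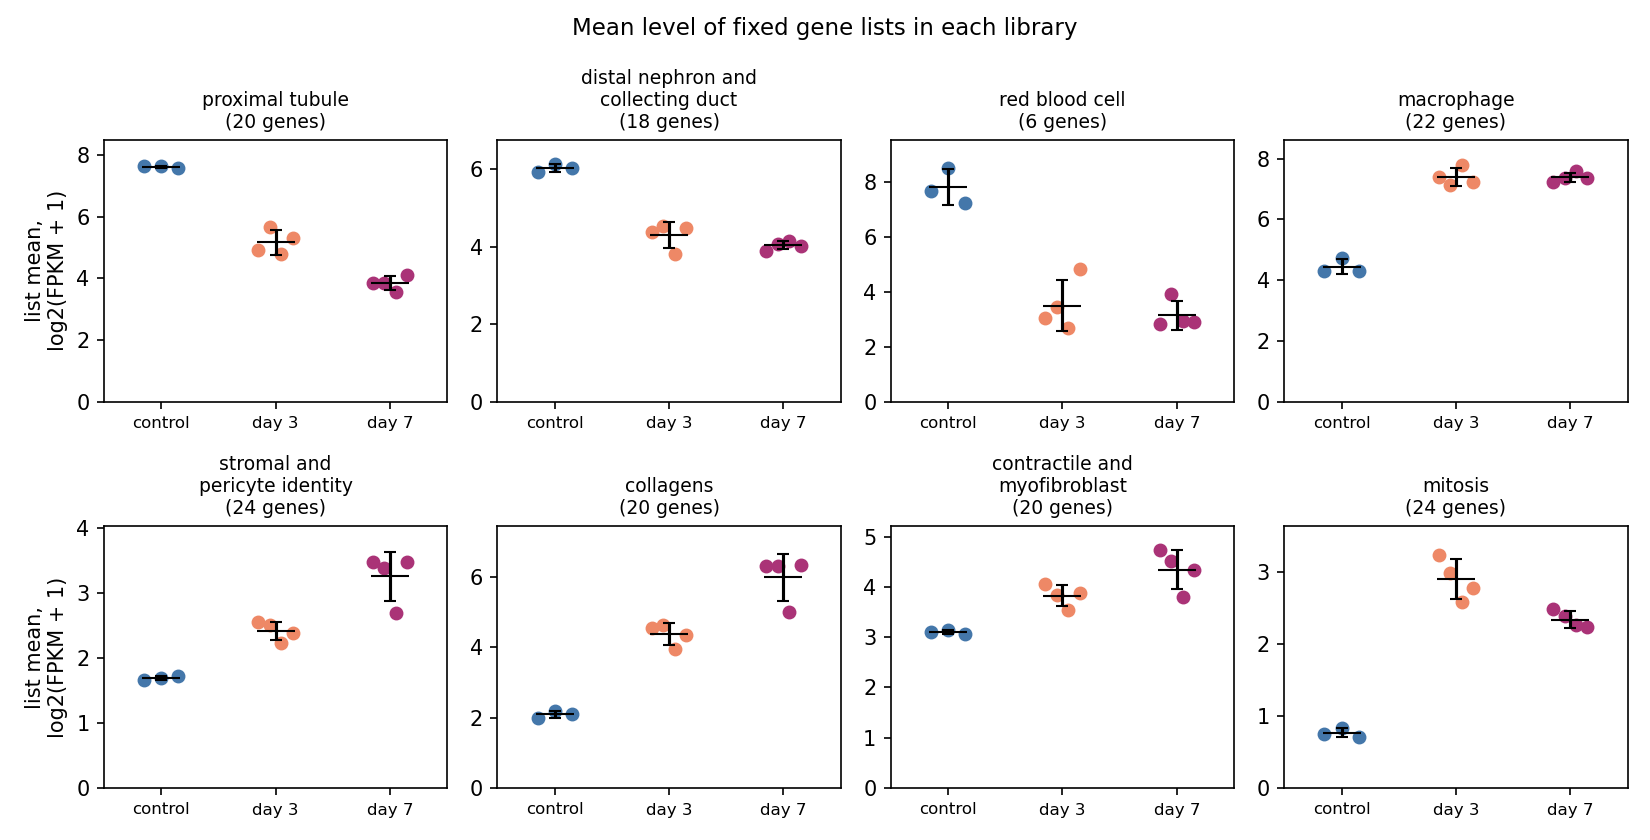
Mean log2(FPKM + 1) of 8 fixed gene lists in each library, as points, with the group mean and SD as the horizontal line and bar. Proximal tubule, distal nephron and red blood cell lists are lower and the macrophage, stromal, collagen, contractile and mitosis lists higher in all UUO libraries than in control; day 7 replicate 3 is the lowest day 7 point of the collagen list at 5 against 6.3 for the next.

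At day 3 after obstruction, matrix, inflammatory, macrophage and cell cycle genes were higher and proximal tubule, mitochondrial and red blood cell genes lower than in control. The largest rise was that of Timp1, an inhibitor of matrix metalloproteinases (ENSMUSG00000001131.11, chromosome X, 20870166 to 20874735 in GRCm38), from 1.36 ± 0.531 to 126 ± 55.5 FPKM (log2 fold change 5.68, SE 0.45, adjusted p = 5.35e-07). Havcr1, which encodes the kidney injury molecule KIM-1 of injured tubule cells (ENSMUSG00000040405.13, chromosome 11, 46735080 to 46779578), went from 0.705 ± 0.187 to 64.2 ± 16.8 FPKM (5.22, SE 0.23, adjusted p = 1.56e-08). Further large rises were those of Fcrls (5.01), the interleukin-1 family cytokine Il1f6 (5.01), the chemokine Pf4 (4.78), the arginine-degrading enzyme Arg1 (4.71), the chemokine Ccl8 (4.64) and Ms4a6d (4.49). The deepest fall was that of Pvalb, the calcium-binding parvalbumin of the distal convoluted tubule (ENSMUSG00000005716.16, chromosome 15, 78191114 to 78206400), from 50.9 ± 6.35 to 0.0447 ± 0.0672 FPKM (−5.63, SE 0.11, adjusted p = 1.65e-11). It was followed by the methyltransferase Inmt (−5.31), the amino acid transporter Slc7a13 (−5.04), the organic anion transporter Slc22a7 (−4.73) and the hemoglobin genes Hba-a2 (−5.28), Hbb-bs (−5.08), Hbb-bt (−5.03) and Hba-a1 (−4.81), which share reads.

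Matrix genes rose at day 3. Of 20 collagens, 18 rose and 2 did not pass, with a median 2.08 above that of all genes (camera adjusted p = 0.000234; adjusted p = 0.551 with an estimated correlation). Examples were the fibrillar collagens Col3a1 (10.1 ± 1.83 to 226 ± 61.2 FPKM, log2 fold change 4.33) and Col1a1 (15.2 ± 4.16 to 295 ± 95.3 FPKM, 4.15). Of 30 other matrix proteins, 26 rose and 4 did not pass (median 1.56 above all genes, adjusted p = 6.19e-05; adjusted p = 0.528 with an estimated correlation), led by fibronectin (Fn1, 4.07) and Tgfbi (4.02). Among 22 matrix proteases and inhibitors, 19 rose, 1 fell and 2 did not pass (median 0.85 above all genes, adjusted p = 0.000872; adjusted p = 0.257 with an estimated correlation), with Mmp19 at 3.78 next to Timp1. In the TGF-beta pathway, 20 of 23 genes rose, and 22 when adjusted over the list alone (median 0.97 above all genes, adjusted p = 0.000148; adjusted p = 0.229 with an estimated correlation), among them Inhba (2.43) and Tgfb1 itself (9.02 ± 2.28 to 46.7 ± 7.04 FPKM, 2.26). These changes stood beside the 22 macrophage markers, all of which rose.

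Some contractile and stromal identity genes rose at day 3, while others fell or did not pass. Acta2, the smooth muscle actin used as a myofibroblast marker (ENSMUSG00000035783.8, chromosome 19, 34241090 to 34255336), went from 30 ± 0.707 to 76.5 ± 19.8 FPKM (log2 fold change 1.28, SE 0.33, adjusted p = 0.00431), and Tagln, which encodes the actin-binding transgelin, from 19.1 ± 0.541 to 51 ± 14.2 FPKM (1.33). Of 20 contractile and myofibroblast genes, 12 rose, 1 fell and 7 did not pass, led by Actg2 (2.03) and Actn1 (1.67), with 8 rises and 3 falls after median centring and 14 and 0 after rescaling to TPM. The list did not pass camera (median 0.45 above all genes, adjusted p = 0.144; adjusted p = 0.794 with an estimated correlation) and passed after quantile normalization (adjusted p = 0.0444) and with fry (0.0045), with p from 0.0444 to 0.202 over the camera alternatives. Of 24 stromal and pericyte genes, 12 rose, 2 fell and 10 did not pass, with 10 rises and 3 falls after median centring and 19 and 0 after rescaling to TPM (median 0.42 above all genes, adjusted p = 0.174; adjusted p = 0.817 with an estimated correlation). Thy1 changed by 2.35 and the transcription factor Snai1 by 1.91. Without day 7 replicate 3, which shares the estimate of the spread, that list passed (adjusted p = 0.0465), as it did with only both groups fitted (0.0425) and with fry (0.00713), with p from 0.0425 to 0.274 over the camera alternatives. The platelet-derived growth factor receptors Pdgfra (0.684 ± 0.0214 to 4.57 ± 1.1 FPKM, 1.70) and Pdgfrb (3.27 ± 0.622 to 11 ± 3.54 FPKM, 1.46) rose. In the Wnt pathway, 10 of 22 genes rose, 9 when adjusted over the list alone, and 3 fell, among them Sfrp4 (1.80) and Wisp1 (1.64) as rises. The Wnt list did not differ detectably from other genes (median 0.06 above all genes, adjusted p = 0.924; adjusted p = 0.995 with an estimated correlation), and its median of 0.32 turned to −0.01 after median centring, with 6 rises and 5 falls.

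Cell cycle and some immune lists rose at day 3. All 24 mitosis genes rose (median 1.78 above all genes, adjusted p = 2.28e-08; adjusted p = 0.231 with an estimated correlation), led by cyclin B2 (Ccnb2, 3.41) and the ubiquitin-conjugating enzyme Ube2c (2.85). Of 27 DNA replication genes, 25 rose, and 26 when adjusted over the list alone (median 1.36, adjusted p = 2.99e-08; adjusted p = 0.231 with an estimated correlation). The helicase subunit Mcm3 (2.57) and the ribonucleotide reductase subunit Rrm2 (2.55) were among the largest changes. Of 29 interferon response genes, 26 rose and 3 did not pass (median 1.33, adjusted p = 3.95e-07; adjusted p = 0.231 with an estimated correlation). Oas1a changed by 3.37 and Ifi27l2a by 3.23. Of 32 inflammatory cytokines and NF-kB targets, 28 rose, 29 when adjusted over the list alone, and 2 fell (median 1.40, adjusted p = 5.46e-06; adjusted p = 0.229 with an estimated correlation). Lipocalin-2 (Lcn2) changed by 4.26 and the monocyte chemoattractant Ccl7 by 4.04. Of 12 complement genes, 8 rose and 2 fell, C3 by the most (4.06), followed by Cfi (2.96). The complement list did not pass camera (median 1.63, adjusted p = 0.13; adjusted p = 0.68 with an estimated correlation) and passed after median centring (0.0237), quantile normalization (0.0293) and with fry (5.35e-05), with p from 0.0237 to 0.281 over the camera alternatives. Of 19 immediate early genes, 18 rose (median 0.91, adjusted p = 4.81e-05; adjusted p = 0.257 with an estimated correlation). Klf4 (3.03) and Fosl1 (2.17) were among the largest changes. Of 21 p53 and senescence genes, 14 rose and 2 fell (median 0.72, adjusted p = 0.0257; adjusted p = 0.231 with an estimated correlation), led by the p53 target genes Mdm2 (2.96) and Bbc3 (2.82), and with the minimum mean raised to 2 FPKM the p was 0.0554, in a range from 0.00613 over the alternatives. All 22 macrophage markers rose (median 2.77, adjusted p = 3.71e-09; adjusted p = 0.256 with an estimated correlation). The integrin Itgam changed by 4.48 and the mannose receptor Mrc1 by 4.03.

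Genes of oxidative metabolism and of the tubule were lower at day 3. All 25 oxidative phosphorylation genes fell (median −1.58 relative to all genes, adjusted p = 4.44e-16; adjusted p = 0.229 with an estimated correlation), as did all 13 genes of the mitochondrial genome (median −2.91, adjusted p = 1.72e-10; adjusted p = 0.231 with an estimated correlation), with mt-Nd3 at −3.01. After quantile normalization the median of these 13 went from −2.65 to −0.74, with 8 called lower. Of 21 fatty acid oxidation genes, 18 fell and 2 rose (median −1.38, adjusted p = 3.71e-09; adjusted p = 0.229 with an estimated correlation). The peroxisomal enzyme Ehhadh changed by −2.30 and the dehydrogenase Acadm by −2.05. In the glycolysis and hypoxia list, 13 genes fell, 14 when adjusted over the list alone, 4 rose and 8 did not pass, but after rescaling to TPM 3 fell and 7 rose and the median turned from −0.41 to 0.02. Its camera call (median −0.67 relative to all genes, adjusted p = 0.0124; adjusted p = 0.599 with an estimated correlation) was lost after that rescaling (0.0512), after quantile normalization (0.0774), with fry (0.248) and without control replicate 2 (0.0537), in a range from 0.00456 to 0.0774 with camera. Hexokinase 2 (Hk2) was among its rises (1.95) and the mitophagy receptor Bnip3 among its falls (−1.10). All 20 proximal tubule markers fell (median −2.74, adjusted p = 1.21e-13; adjusted p = 0.229 with an estimated correlation). The cytochrome P450 Cyp4b1 (−3.99) and Kap (−3.67) were among the largest changes. Of 18 distal nephron and collecting duct markers, 16 fell, 17 when adjusted over the list alone, and 1 rose (median −1.68, adjusted p = 2.28e-08; adjusted p = 0.229 with an estimated correlation), with calbindin (Calb1) at −3.49 after Pvalb.

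Markers of other cells at day 3 moved in different directions. Of 10 podocyte markers, 7 fell and 1 rose (median −1.68, adjusted p = 8.43e-05; adjusted p = 0.229 with an estimated correlation), among them Clic3 (−3.34). All 6 red blood cell markers fell (median −5.18, adjusted p = 3.47e-05; adjusted p = 0.231 with an estimated correlation). Of 22 markers of general and injured epithelium, 9 rose, 4 fell and 9 did not pass, with Sox9, a transcription factor of injured tubule, at 3.12 next to Havcr1. The mean of this list was 0.62 and its median 0.13, or −0.13 relative to all genes, and the median turned to −0.20 after median centring, with 6 rises and 8 falls (camera adjusted p = 0.984; adjusted p = 0.995 with an estimated correlation). With fry, which does not compare a list with other genes, it passed as up (0.00764), while camera gave 0.407 to 0.998 over the alternatives. Of 18 endothelial markers, 6 rose, 4 fell and 8 did not pass, with Ehd3 at −1.81 and the lymphatic receptor Flt4 at 0.83. Their median was 0.20 and camera's direction down, and after median centring the median was −0.14 with 4 rises and 7 falls (adjusted p = 0.63; adjusted p = 0.916 with an estimated correlation).

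In all, 8773 of 13428 genes (65.3%) were called at day 3, 5957 higher and 2816 lower, and 3483 of these changed at least 2-fold. The split depended on scaling: 3743 were higher and 4701 lower after median centring, 4146 and 4358 after quantile normalization, and 8438 and 1822 after rescaling to TPM. Of the 39 lists, 24 were called by camera, 15 up and 9 down, 0 with an estimated correlation (8 at an unadjusted p under 0.05) and 29 by fry.

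At day 7 after obstruction, matrix genes stood among the largest rises. Col1a1 (ENSMUSG00000001506.10, chromosome 11, 94936224 to 94953042) went from 15.2 ± 4.16 FPKM in control to 1240 ± 452 (log2 fold change 6.18, SE 0.36, adjusted p = 3.97e-08) and Col3a1 (ENSMUSG00000026043.18, chromosome 1, 45311538 to 45349706) from 10.1 ± 1.83 to 788 ± 295 (6.05, SE 0.33, adjusted p = 2.69e-08). Timp1 (258 ± 187 FPKM, 6.54), Ccl8 (130 ± 49.7 FPKM, 6.42), Arg1 (117 ± 70.6 FPKM, 6.40), Fn1 (209 ± 78.9 FPKM, 5.75), the matricellular protein periostin (Postn, 0.526 ± 0.066 to 88 ± 56.6 FPKM, 5.68) and Col5a1 (133 ± 56.3 FPKM, 5.67) completed the 8 largest rises. The lowest day 7 values of Col1a1 and Col3a1, 563 and 348 FPKM, were those of replicate 3. The largest falls were those of Hba-a2 (−5.68), Pvalb (−5.62), Slc7a13 (−5.53), Hbb-bs (−5.45), Hbb-bt (−5.41), the inositol oxygenase Miox of the proximal tubule (−5.27), Inmt (−5.25) and Hba-a1 (−5.22).

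Nearly every matrix gene on the lists was higher at day 7. Of 20 collagens, 19 rose (median 3.98 above all genes, adjusted p = 1.8e-06; adjusted p = 0.355 with an estimated correlation), including Col1a2 (9.18 ± 2 to 505 ± 184 FPKM, 5.55), and all 30 other matrix proteins rose (median 3.39, adjusted p = 5.18e-09; adjusted p = 0.26 with an estimated correlation). Of 22 matrix proteases and inhibitors, 19 rose and 1 fell (median 1.96, adjusted p = 0.000108; adjusted p = 0.26 with an estimated correlation), with the gelatinase Mmp2 at 4.65. In the TGF-beta pathway, 21 of 23 genes rose (median 1.19, adjusted p = 9.25e-06; adjusted p = 0.258 with an estimated correlation). The latent TGF-beta binding protein Ltbp2 changed by 4.28 and Tgfb3 by 3.62, while Tgfb1 stood at 43.5 ± 5.06 FPKM (2.17). Of 20 contractile genes, 14 rose and 6 did not pass (median 1.17, adjusted p = 0.0142; adjusted p = 0.563 with an estimated correlation), with Actg2 at 4.06, Tagln at 2.30 (106 ± 44.7 FPKM) and Acta2 at 2.06 (140 ± 62.3 FPKM). Of 24 stromal and pericyte genes, 19 rose and 1 fell (median 1.29, adjusted p = 0.00249; adjusted p = 0.502 with an estimated correlation), with dermatopontin (Dpt) at 4.34, Thy1 at 3.71, Pdgfra at 2.64 and Pdgfrb at 2.16. In the Wnt pathway, 17 of 22 genes rose and 1 fell (median 1.17, adjusted p = 0.0105; adjusted p = 0.563 with an estimated correlation). The Wnt-induced secreted proteins Wisp2 (3.03) and Wisp1 (2.99) were among the largest changes. Replicate 3 was the lowest day 7 library for the collagen, other matrix and stromal list means.

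**Figure D3:**
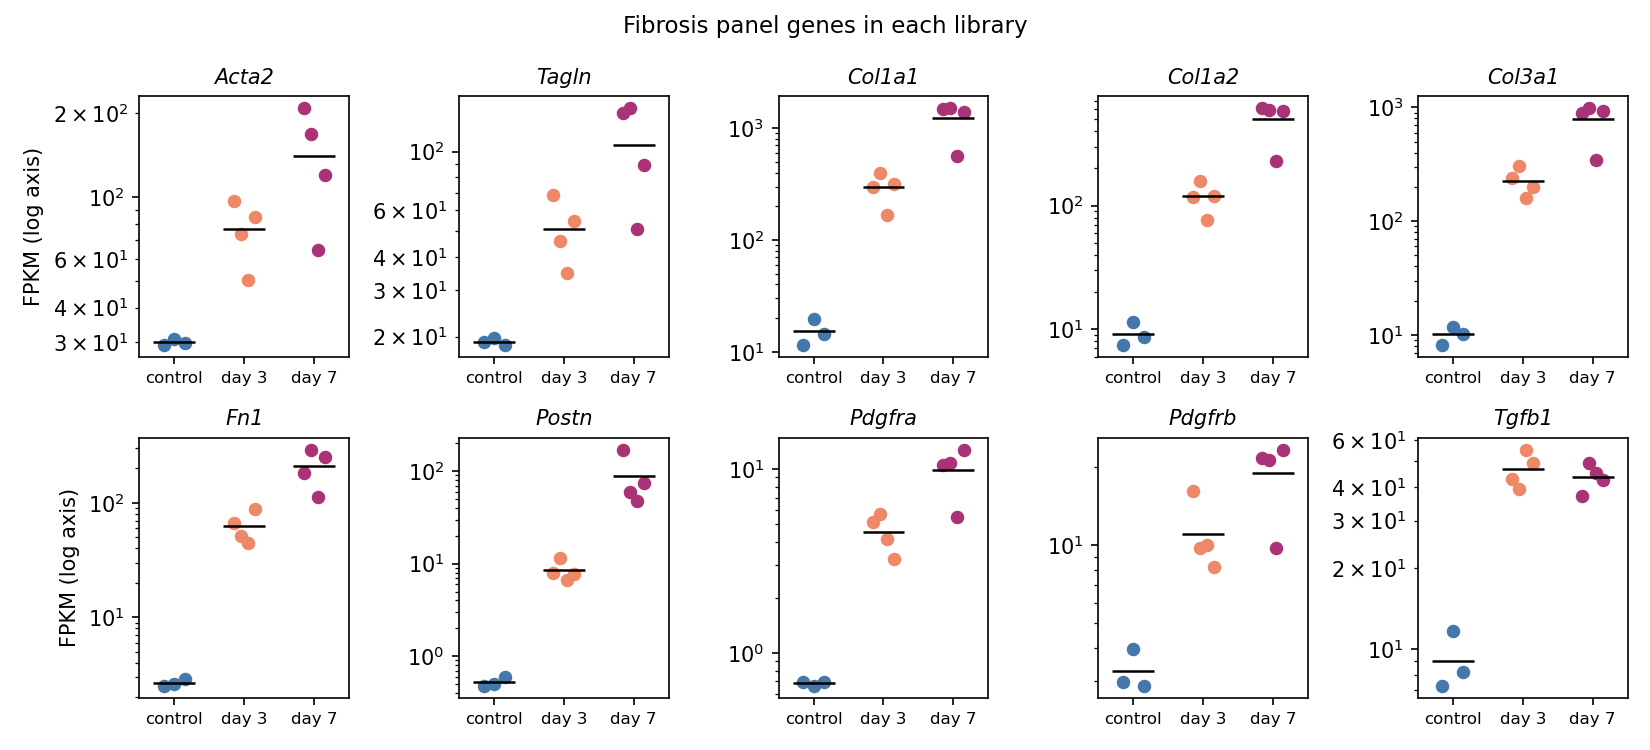
FPKM of the 10 panel genes in each library on a log axis, as points, with the group mean of 3 control, 4 day 3 and 4 day 7 libraries as a line. All 10 were called higher at day 3 and at day 7 than in control; Tgfb1 averaged 46.7 FPKM at day 3 and 43.5 FPKM at day 7, whereas Postn averaged 8.49 and 88 FPKM.

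Cell cycle and some immune lists also exceeded control at day 7. All 22 macrophage markers rose (median 2.78 above all genes, adjusted p = 2.76e-08; adjusted p = 0.26 with an estimated correlation). Itgam changed by 5.06 and Mrc1 by 4.55. Of 32 inflammatory genes, 29 rose and 1 fell (median 1.40, adjusted p = 6.76e-06; adjusted p = 0.258 with an estimated correlation). The chemokines Ccl7 (4.94) and Ccl2 (4.67) were among the largest changes. Of 29 interferon response genes, 27 rose and 1 fell (median 1.10, adjusted p = 6.34e-06; adjusted p = 0.26 with an estimated correlation). Oas1a changed by 3.08 and Ifi27l2a by 2.89. Of 12 complement genes, 10 rose and 1 fell (median 2.05, adjusted p = 0.0104; adjusted p = 0.42 with an estimated correlation). C4b changed by 4.26 and C1s1 by 3.86. All 24 mitosis genes rose (median 1.28, adjusted p = 6.76e-06; adjusted p = 0.275 with an estimated correlation), with Ccnb2 at 2.31 and the topoisomerase Top2a at 2.05, and 25 of 27 DNA replication genes rose (median 0.92, adjusted p = 1.07e-05; adjusted p = 0.26 with an estimated correlation). Cyclin E1 (Ccne1) changed by 2.17 and Rrm2 by 2.16. Immediate early genes rose in 18 of 19 cases (median 1.45, adjusted p = 3.9e-06; adjusted p = 0.26 with an estimated correlation). Klf4 changed by 3.65 and Egr2 by 3.40. Of 21 p53 and senescence genes, 16 rose and 2 fell (median 0.73, adjusted p = 0.0104; adjusted p = 0.258 with an estimated correlation). The apoptosis gene Pmaip1 changed by 3.00 and the kinase Plk2 by 2.73.

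Tubule and oxidative genes were lower at day 7. All 20 proximal tubule markers fell (median −4.23 relative to all genes, adjusted p = 2.78e-15; adjusted p = 0.258 with an estimated correlation), with Miox going from 780 ± 111 to 19.4 ± 4.01 FPKM and Kap at −4.64, and 17 of 18 distal markers fell while 1 rose (median −2.03, adjusted p = 6.28e-08; adjusted p = 0.258 with an estimated correlation), with the anion exchanger Slc4a1, which is also on the red blood cell list, at −3.57. All 25 oxidative phosphorylation genes fell (median −2.04, adjusted p = 4.34e-16; adjusted p = 0.258 with an estimated correlation), such as Ndufb9 (−2.22) and Uqcrq (−2.14), and all 13 mitochondrial genome genes fell (median −3.16, adjusted p = 1.16e-09; adjusted p = 0.26 with an estimated correlation), with mt-Nd3 at −3.46. After quantile normalization the median of the latter went from −2.88 to −1.24, with 12 called lower. Of 21 fatty acid oxidation genes, 18 fell and 1 rose (median −1.80, adjusted p = 3.19e-09; adjusted p = 0.258 with an estimated correlation). Ehhadh changed by −3.58 and Acadm by −2.42. In the glycolysis and hypoxia list, 13 fell and 6 rose as deposited, and 7 fell and 9 rose after rescaling to TPM. Its call (median −0.81, adjusted p = 0.0109; adjusted p = 0.563 with an estimated correlation) was lost after quantile normalization (0.0791, the highest in a range from 0.00377) and with fry (0.0822). Of 10 podocyte markers, 6 fell and 1 rose (median −1.20, adjusted p = 0.00413; adjusted p = 0.26 with an estimated correlation). Clic3 changed by −3.12. All 6 red blood cell markers fell (median −5.59, adjusted p = 7.4e-05; adjusted p = 0.26 with an estimated correlation). Of 22 epithelial markers, 6 rose, led by Havcr1 (5.16) and keratin 20 (Krt20, 2.87), and 8 fell. Their mean was 0.35, their median −0.26 and camera's direction down, while fry's was up, and after rescaling to TPM the median was 0.18 with 9 rises and 4 falls (adjusted p = 0.296; adjusted p = 0.804 with an estimated correlation). Of 18 endothelial markers, 7 rose and 3 fell, with Ehd3 at −1.69 and VE-cadherin (Cdh5) at 0.98. Their median was 0.24 with camera's direction down, and it turned to −0.06 after median centring, with 6 rises and 7 falls (adjusted p = 0.877; adjusted p = 0.941 with an estimated correlation).

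At day 7, 9379 genes (69.9%) were called, 6217 higher and 3162 lower, of which 4124 changed at least 2-fold. The numbers called were 4251 higher and 4654 lower after median centring, 4535 and 4512 after quantile normalization, and 8842 and 2087 after rescaling to TPM. By camera 28 of the 39 lists were called, 18 up and 10 down, 0 with an estimated correlation (6 at an unadjusted p under 0.05) and 32 by fry.

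**Figure D4:**
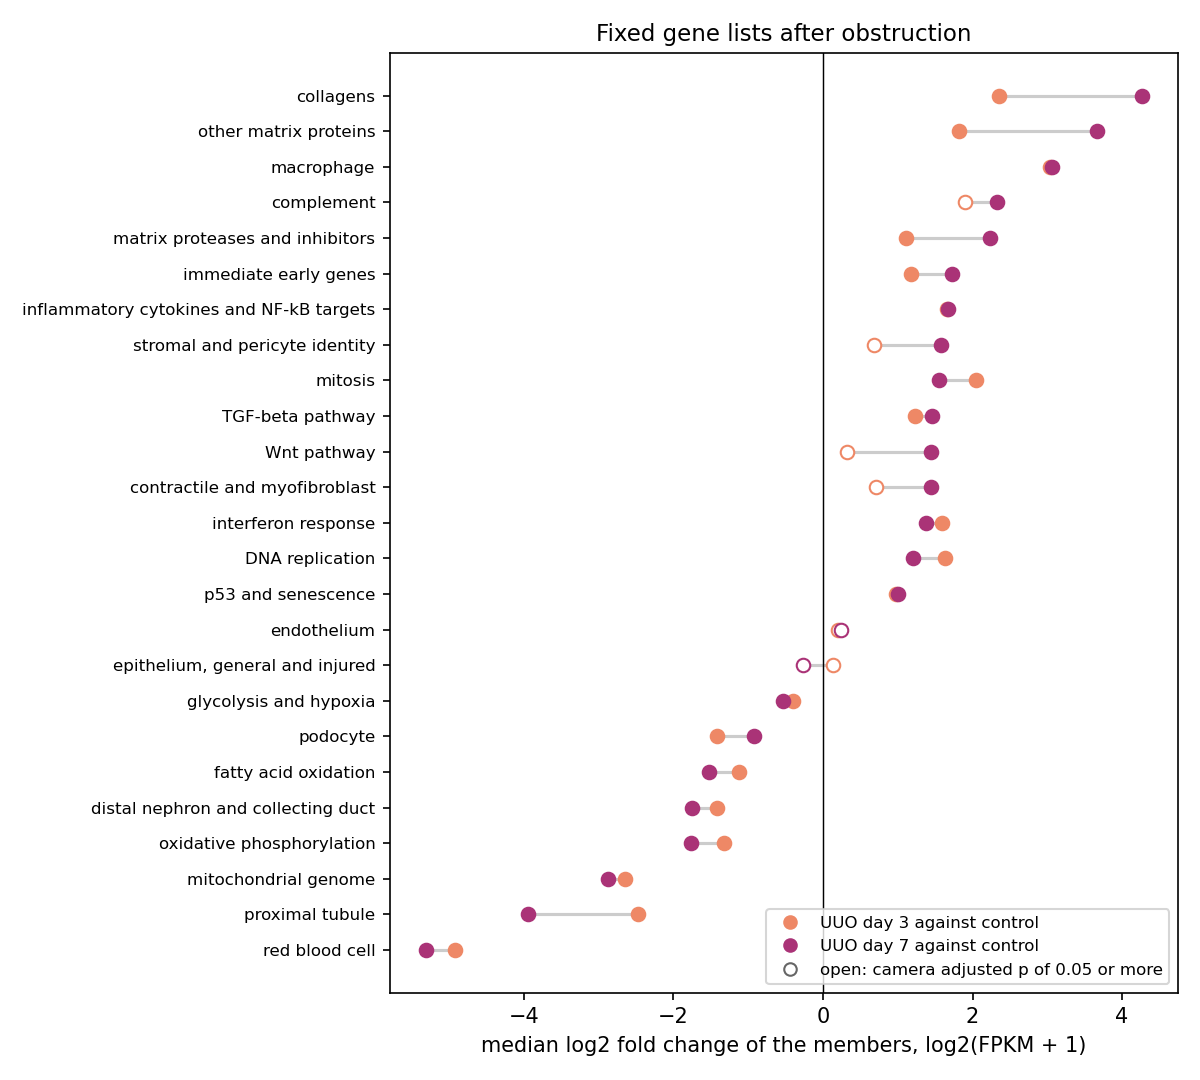
Median log2 fold change of the members of 25 lists, on the log2(FPKM + 1) scale, at day 3 (orange) and day 7 (purple) against control, with a grey line joining both times and open points for lists that camera did not call. The collagen median was 2.35 at day 3 and 4.26 at day 7 and the proximal tubule median −2.48 and −3.95, while the sign of the epithelial and endothelial medians at both times, and of the Wnt and glycolysis medians at day 3, changes with the scaling.

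Between day 3 and day 7, most collagens and other matrix proteins rose further. Most proximal tubule markers and some cell cycle genes fell, and macrophage markers were not detectably different. The largest rises were those of Retnla, a product of alternatively activated macrophages and adipose tissue (ENSMUSG00000061100.3, chromosome 16, 48842552 to 48844461), from 2.57 ± 2.11 to 48.5 ± 9.14 FPKM (log2 fold change 3.95, SE 0.31, adjusted p = 6.82e-05), the complement protease adipsin (Cfd, 3.78), asporin (Aspn, 3.67), Itm2a (3.51) and elastin (Eln, 6.51 ± 2.93 to 80.8 ± 34.9 FPKM, 3.40). The largest falls were those of the fibrinogen chain gene Fga (ENSMUSG00000028001.16, chromosome 3, 83026076 to 83033627), from 37.3 ± 5.04 to 6.54 ± 1.74 FPKM (−2.36, SE 0.17, adjusted p = 6.82e-05), its neighbour Fgg (44.5 ± 5.15 to 8.63 ± 1.78 FPKM, −2.25), the retinol dehydrogenase Rdh16f2 (−2.33), Spp2 (−2.18) and the steroid dehydrogenase Hsd3b4 (−2.06). Fga and Fgg averaged 2.85 and 1.36 FPKM in control.

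Of 20 collagens, 16 rose from day 3 to day 7, 17 when adjusted over the list alone (median 1.88 relative to all genes, camera adjusted p = 1.01e-14; adjusted p = 0.225 with an estimated correlation). Col8a2 (3.03) and Col8a1 (2.80) were among the largest changes. Of 30 other matrix proteins, 25 rose, 28 when adjusted over the list alone, and 1 fell (median 1.66, adjusted p = 9.82e-22; adjusted p = 0.207 with an estimated correlation). Of 22 proteases and inhibitors, 11 rose and 2 fell, or 14 and 3 when adjusted over the list alone (median 0.79, adjusted p = 1.24e-07; adjusted p = 0.207 with an estimated correlation). Mmp2 changed by 2.73 and cathepsin K (Ctsk) by 1.87. Of 24 stromal and pericyte genes, 13 rose, 19 when adjusted over the list alone (median 0.75, adjusted p = 4.86e-11; adjusted p = 0.225 with an estimated correlation). Dpt changed by 2.67 and Pi16 by 2.08. In the Wnt pathway, 17 of 22 rose, 19 when adjusted over the list alone, and 1 fell (median 1.11, adjusted p = 1.13e-12; adjusted p = 0.207 with an estimated correlation), led by the secreted frizzled-related protein Sfrp2 (3.14). In the TGF-beta pathway, 9 of 23 rose, 13 when adjusted over the list alone, and 1 fell (median 0.43, adjusted p = 1.38e-05; adjusted p = 0.207 with an estimated correlation), with Ltbp2 at 2.43 and Tgfb3 at 2.01, while Tgfb1 differed by −0.09 (adjusted p = 0.719).

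Some contractile genes rose between the days. Of 20, 6 rose and 14 did not pass (median 0.55 relative to all genes, adjusted p = 0.000424; adjusted p = 0.409 with an estimated correlation), led by Actg2 (2.03) and calponin (Cnn1, 1.42), and fry gave 0.0902, against 6.56e-07 to 0.00548 over the camera alternatives. Acta2 differed by 0.78 (adjusted p = 0.108), but by 1.11 without day 7 replicate 3 (0.00558), and it passed with sample weights (0.64, 0.0315), in a range of p from 0.00558 to 0.284. Tagln differed by 0.97 (adjusted p = 0.0426), a call lost with only both groups fitted (0.08), with values from the transcript table (0.0512) and in 9 of the 11 fits that left out a library: any control library, day 3 replicates 2 to 4 and day 7 replicates 1, 2 and 4, with p from 0.0549 to 0.128, in a range from 0.00214 over all alternatives. Pdgfrb differed by 0.70 (adjusted p = 0.0879), and by 0.98 without day 7 replicate 3 (0.00448) and 0.89 without day 3 replicate 1 (0.0389), and it passed with sample weights (0.83, 0.00787), in a range of p from 0.00448 to 0.219. Pdgfra (0.93, adjusted p = 0.0112), Col1a1 (2.03), Col1a2 (2.02), Col3a1 (1.73), Fn1 (1.68) and Postn (3.07) were higher at day 7 than at day 3.

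Of 24 mitosis genes, 11 fell, 17 when adjusted over the list alone and 7 after rescaling to TPM (median −0.51 relative to all genes, adjusted p = 5.94e-08; adjusted p = 0.28 with an estimated correlation), such as Ccnb2 (−1.10) and survivin (Birc5, −0.94). Of 27 DNA replication genes, 13 fell, 16 when adjusted over the list alone, and 1 rose (median −0.36, adjusted p = 8.34e-06; adjusted p = 0.297 with an estimated correlation). Mcm5 changed by −0.87 and Uhrf1 by −0.76. Of 19 immediate early genes, 10 rose, 11 when adjusted over the list alone (median 0.52, adjusted p = 6.65e-09; adjusted p = 0.207 with an estimated correlation). Egr2 changed by 1.32 and Egr3 by 1.25. Of 12 complement genes, 6 rose and 1 fell (median 0.73, adjusted p = 0.00155; adjusted p = 0.326 with an estimated correlation), with C1s1 at 1.83. Of 32 inflammatory genes, 6 rose and 2 fell, or 8 and 5 when adjusted over the list alone, with the prostaglandin synthase Ptgs2 at 1.22. The inflammatory call (median 0.29, adjusted p = 0.0481; adjusted p = 0.448 with an estimated correlation) was lost after each other scaling but quantile normalization, with no filter on low values (0.0583), with only both groups fitted (0.0507), with fry (0.114) and without control replicate 1 (0.0532) or 2 (0.0543), day 3 replicate 1 (0.175) or 2 (0.0697) or day 7 replicate 2 (0.274), in a range from 0.00909. Of 21 p53 and senescence genes, 5 rose, and 6 rose and 1 fell when adjusted over the list alone (median 0.11, adjusted p = 0.055; adjusted p = 0.297 with an estimated correlation). Phlda3 (1.07) and the cell cycle inhibitor gene Cdkn2a (0.91) were among the largest changes. That list passed with fry (0.018), after quantile normalization (0.0319) and without day 3 replicate 4 (0.0274), day 7 replicate 3 (0.0439) or day 7 replicate 4 (0.0396), in a range from 0.0274 to 0.124. Of 29 interferon response genes 1 rose and 1 fell, and 0 passed with limma when adjusted over the list alone, with 4 at an unadjusted p under 0.05 (median −0.07, adjusted p = 0.353; adjusted p = 0.792 with an estimated correlation).

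All but 1 of the 20 proximal tubule markers fell further between the days, and all 20 when adjusted over the list alone (median −1.26 relative to all genes, adjusted p = 1.16e-15; adjusted p = 0.207 with an estimated correlation). Miox (−1.96) and the urate transporter Slc22a12 (−1.95) were among the largest changes. Of 18 distal markers, 3 fell (median −0.06, adjusted p = 0.194; adjusted p = 0.641 with an estimated correlation), with the water channel Aqp2 at −1.59, and the list passed without day 3 replicate 3 (0.0222) and with sample weights (0.0259), in a range to 0.416. The change of the proximal list mean exceeded that of the distal list mean by −1.07 (exact permutation p = 0.0286, two-sided, the smallest possible for 4 against 4 libraries). Of 25 oxidative phosphorylation genes, 13 fell, and 24 when adjusted over the list alone (median −0.37, adjusted p = 2.55e-08; adjusted p = 0.32 with an estimated correlation). Of 21 fatty acid oxidation genes, 5 fell, 7 when adjusted over the list alone, and 1 rose (median −0.30, adjusted p = 0.000937; adjusted p = 0.409 with an estimated correlation), with Ehhadh at −1.28. In the mitochondrial genome 1 of 13 genes fell (median −0.27, adjusted p = 0.0347; adjusted p = 0.599 with an estimated correlation), a list call lost at a minimum mean of 2 FPKM (0.0625), with fry (0.224) and without day 3 replicate 3 (0.145), day 7 replicate 2 (0.209) or day 7 replicate 4 (0.128), in a range from 0.00031. Of 25 glycolysis and hypoxia genes, 2 rose and 2 fell, or 2 and 3 when adjusted over the list alone (median −0.11, adjusted p = 0.557; adjusted p = 0.864 with an estimated correlation), with Ndrg1 at −0.89.

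None of the 22 macrophage markers was called between the days by limma, also when adjusted over the list alone, while 5 had an unadjusted p under 0.05 (median −0.04 relative to all genes, mean −0.004 with camera's direction up and fry's down, adjusted p = 0.767; adjusted p = 0.933 with an estimated correlation), but without day 3 replicate 3 the list passed as higher at day 7 (0.048, in a range to 0.93). Of 22 epithelial markers, 4 fell, 7 when adjusted over the list alone, and 1 rose (median −0.27, adjusted p = 0.0161; adjusted p = 0.524 with an estimated correlation), with prominin-1 (Prom1) at −0.80, a list call lost with fry (0.102) and without day 3 replicate 4 (0.1), in a range from 0.00132. Of 10 podocyte markers, 2 rose, 4 when adjusted over the list alone (median 0.29, adjusted p = 0.00569; adjusted p = 0.28 with an estimated correlation): Wt1, which is also on the mesothelium list, at 0.90 and Cdkn1c at 0.85. Of 18 endothelial markers 1 was called higher, and 0 by limma when adjusted over the list alone, with 4 at an unadjusted p under 0.05 (median 0.09, adjusted p = 0.247; adjusted p = 0.763 with an estimated correlation), and the list passed without day 7 replicate 3 (0.0246) and with sample weights (0.0344), in a range to 0.729. None of the 6 red blood cell markers was called by limma, and 0 had an unadjusted p under 0.05 (median −0.34, adjusted p = 0.499; adjusted p = 0.801 with an estimated correlation).

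Between the days, 2114 genes (15.7%) were called, 990 higher and 1124 lower at day 7, and 496 of them differed at least 2-fold. The balance turned with scaling, to 1120 higher and 960 lower after median centring and 1199 and 920 after rescaling to TPM, and stayed at 1049 and 1194 after quantile normalization. It also turned in 6 of the 11 fits that left out a library, with 806 higher and 614 lower without day 3 replicate 2 and 1085 and 840 without day 7 replicate 3, while 969 and 1630 were called without day 3 replicate 3. The number called fell to 1366 without day 7 replicate 4 and to 1403 without day 7 replicate 1, and rose to 4453 with sample weights (1670 higher and 2783 lower). By camera 25 of the 39 lists were called, 15 up and 10 down, 0 with an estimated correlation (8 at an unadjusted p under 0.05) and 23 by fry.

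Against the shared controls, 7960 genes were called at both times, 5370 higher in both, 2578 lower in both and 12 in opposite directions. The genes called the same way were 3287 higher and 4138 lower after median centring, 3640 and 3917 after quantile normalization, and 7953 and 1665 after rescaling to TPM. Independent lists of these sizes would share 2758 higher and 663 lower genes, and 20 simulations of unchanged groups gave on average 0 genes called the same way. The simulations drew all libraries, the shared controls included, independently for each gene and without pairing by replicate number. With no change put in, a count near 0 was fixed in advance, and a chance deviation of the real controls was not represented. The log2 fold changes at day 3 and day 7 correlated at 0.933 across genes, against 0.573 in the simulations, and had the same sign in 91.2% of genes, against 69.4%. Their covariance was 1.052, against 0.0227 simulated, a difference of 1.029. With 3 control libraries the controls could not be split, so part of the excess may come from the shared controls. Of the 990 genes higher at day 7 than at day 3, 905 were also called higher at day 7 than in control. Of the 1124 genes lower at day 7 than at day 3, 731 were called lower at day 7 than in control and 363 had been called higher at day 3.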

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

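All tests of explanations below were chosen after the result was seen, except the counts over other splits of the samples and the test on the liver list, whose 24 genes were listed without looking at their values although the pattern had been seen.

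The libraries named fibroblasts held abundant tubule transcripts, which fell after obstruction while macrophage and matrix transcripts rose. RNA of other kidney cells may account for the tubule transcripts: 20 of 20 proximal tubule markers, 18 of 18 distal nephron markers and 7 of 10 podocyte markers stood at 5 FPKM or more in control, with Kap at 11100, Umod at 1070 and Podxl at 62.7 FPKM. Per the labels the digested tissue was enriched in culture medium, and they name no sort that would remove such cells. A lower share of tubule RNA alone would raise the other cell types alike, but from control to day 7 the macrophage list mean rose by 2.94 (4.293 to 4.735 in control libraries, 7.233 to 7.577 at day 7) and the endothelium list mean by 0.13 (2.778 to 2.965 and 2.699 to 3.176), a gap of 2.81. A higher share of stromal RNA alone would raise collagens and stromal identity genes alike. The collagen minus stromal identity mean went from 0.39 ± 0.08 to 2.73 ± 0.3 (SD, n = 3 and 4), a change of 2.34. It changed by 2.71 for the 14 collagens and 15 stromal genes at 1 FPKM or more in control. The collagens thus rose more than the stromal genes listed. That does not settle the matter, since the list may not follow the stromal share. Only 4 of its 24 genes stood at 5 FPKM or more in control, and its highest, Ly6a, stood at 188 FPKM in control and 169 at day 7. Exact permutation p was 0.0286 for 2.81 and for 2.34 (two-sided, the smallest possible for 3 against 4 libraries), over splits that take no account of replicate numbers, and the 8 splits that part as many pairs as the real one are too few for a p under 0.05. A higher share of stromal RNA stays open. So do a mixture in which several cell shares and the expression within cells change at once and the effect of obstruction itself.

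Day 7 replicate 3 was the lowest day 7 library in matrix genes. Its gap to the next library, divided by the range of the 4, exceeded Dixon's 95% critical value for the list means of collagens (0.963; 5 against 6.3), other matrix proteins (0.945; 4.84 against 5.83) and stromal genes (0.873; 2.7 against 3.38), and for Col1a1 (0.885; 563 against 1390 FPKM), Col1a2 (0.922; 229 against 581), Col3a1 (0.867; 348 against 898), Pdgfrb (0.844; 9.72 against 21.2), Mmp2 (0.954; 48.2 against 112) and Clic3 (0.83). The scale of the whole library is argued against by a median difference of 0.013 over all tested genes beside −1.38 for the collagens, and a day 3 sample under a day 7 label by a proximal tubule mean of 3.55, below the day 3 range of 4.79 to 5.66, and a mitosis mean of 2.27 against at least 2.59, although its highest correlation with a day 3 library (0.965) was no lower than its lowest with a day 7 library (0.965). A smaller share of stromal RNA in this library cannot be told apart from lower expression, since the stromal genes lay lower by a median of −1 (SD 0.55 over 13 genes) and the collagens by −1.38 (SD 0.43 over 19), a gap within the spread of the genes. A difference between animals was not tested, and the macrophage mean of 7.58 lay above those of the other day 7 libraries, at most 7.37.

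In day 3 replicate 1, 39 genes stood at 5 FPKM or more and at least 10 times above every other library, among them Alb (261 against at most 3.04 FPKM), Mup7 (79 against 0.16), Fabp1 (52.1 against 0.852), Apoa1 (47.5 against 0.625) and Serpina3k (32 against 0.0564). Control replicate 1 held 1 such gene, Krt12 (6.64 against 0.284), and the other 9 libraries 0. Liver RNA in this library may account for them: 14 of 24 liver genes, of which 19 are in the table, stood at more than 3 times the highest other day 3 library, against 112 of all 13985 genes (0.801%), and the other 5 listed genes, which did not, include some that were also abundant in another day 3 library, such as Gc (48.9 against 37 FPKM) and Ttc36 (48.5 against 80). Reads shared between copies of the major urinary protein genes are argued against as the whole cause, because 21 of the 39 genes lie outside that family and 18 within it. Whether such RNA entered with the tissue or at a later step was not tested, and no biological explanation was tested.

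Other single libraries stood apart by the same measure, in all 26 of 260 pairs of a named gene with a UUO group and 4 of 50 list means, where about 1 in 20 groups is past this value by chance. At day 3, replicate 4 was the highest for Hba-a2 (0.844), Hbb-bs (0.842), Hbb-bt (0.872) and Hba-a1 (0.834), which share reads, and the lowest for Klf4 (0.917) and Tgfb3 (0.941). Replicate 1 was the highest for Thy1 (0.855), replicate 2 the lowest for Ccl8 (0.861) and the highest for Dpt (0.847) and mt-Co3 (0.878), and replicate 3 the highest for Cxcl5 (0.867) and Cd74 (0.87). At day 7, replicate 2 was the highest for the red blood cell list mean (0.902; 3.93 against 2.93), Hba-a2 (0.908), Hbb-bs (0.982), Hbb-bt (0.949), Hba-a1 (0.933), Rrm2 (0.945) and Bnip3 (0.915). Replicate 3 was the highest for Il1f6 (0.853; 72.2 against 19.6 FPKM) and Aqp4 (0.964).

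The day 7 minus day 3 effect differed from 0 by limma for 41 of 88 genes named for the comparisons with control (adjusted p 6.82e-05 to 0.0426). Naming by large changes may favour such genes, and 15.7% of all genes tested differed. Matrix and stromal genes were further up at day 7: Col1a1 (2.03), Col1a2 (2.02), Col3a1 (1.73), Col5a1 (1.98), Fn1 (1.68), Postn (3.07), Mmp2 (2.73), Dpt (2.67), Thy1 (1.36), Pdgfra (0.93), Snai1 (0.93), Ltbp2 (2.43), Tgfb3 (2.01), Inhba (1.00), Wisp1 (1.35), Wisp2 (2.01), Actg2 (2.03) and Tagln (0.97), while Tgfbi was less so (−0.56). Among immune and stress genes, Arg1 (1.69), Ccl8 (1.78), Ccl7 (0.9), Ccl2 (0.85), C4b (1.52), C1s1 (1.83), Klf4 (0.62), Egr2 (1.32), Plk2 (0.53) and Krt20 (0.93) had the larger effect at day 7, and Cfi (−1.31) the smaller. The Krt20 call was lost without day 7 replicate 1 (0.85, adjusted p = 0.0556, the highest in a range from 0.00184). The cell cycle genes Ccnb2 (−1.1), Ube2c (−0.91), Mcm3 (−0.68) and Top2a (−0.57) rose less at day 7, and Ccne1 (0.42) more. The tubule and metabolic genes Slc22a7 (−0.49), Kap (−0.97), Miox (−1.96), Ehhadh (−1.28), Ndufb9 (−0.49) and Ndrg1 (−0.89) were lower still. Of the 25 lists described, 18 differed by camera, and none with an estimated correlation (adjusted p 0.207 to 0.599). These 18 had a median difference of 1.83 for collagens, 1.61 for other matrix proteins, 0.75 for proteases and inhibitors, 0.5 for contractile genes, 0.39 for the TGF-beta pathway, 0.71 for stromal genes, 1.06 for the Wnt pathway, 0.47 for immediate early genes, 0.69 for complement, 0.24 for inflammatory genes, 0.24 for podocyte markers, −0.56 for mitosis, −0.41 for DNA replication, −0.42 for oxidative phosphorylation, −0.34 for fatty acid oxidation, −0.31 for the mitochondrial genome, −1.3 for proximal tubule and −0.32 for epithelium.

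Over splits that ignore replicate numbers, the real split gave the most genes called in each comparison, a share under 0.05. Because the replicates may not be separate animals, this does not exclude a chance difference between animals or preparations. Of 35 splits into groups of the same sizes, only the real one gave as many calls at day 3 (8773, highest other 5473), at day 7 (9379, highest other 5091) and between the days (2114, highest other 3). Of 100 drawn splits, it alone gave as many genes called the same way at both times (7948, highest other 143). Drawn splits also lose the calls of each comparison, so this does not test agreement of both times. For the numbers of lists called, chance was not excluded: 5 of 35 splits gave as many at day 3 (24; highest other 28), 6 of 35 at day 7 (28; highest other 31) and 3 of 35 between the days (25; highest other 31). For day 7 with control, treated as paired by replicate number, the real split parts 3 pairs. Of the 8 splits that part as many, only the real one gave as many calls (highest other 3010). These 8 are too few for a share under 0.05.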

How the results depend on the processing

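All alternatives but leaving out the mitochondrial genome were fixed beforehand. None of the genes and of the 25 lists followed through these fits changed direction where either fit called it, the direction of a list being that given by camera or fry. The other 14 of the 39 lists entered only the counts of lists and the medians after scaling. Medians did change sign, as at day 3 for glycolysis and hypoxia (−0.41, and 0.02 with TPM) and between the days for macrophage markers (−0.042 relative to all genes, and 0.065 without day 3 replicate 3). Among genes named but not followed, Inpp5b, Fgf11 and Pklr at day 7 changed sign with scaling (−0.28 to 0.17 with TPM, 0.26 to −0.05 after median centring and −0.36 to 0.03 with TPM). Among all genes called in both fits, values summed from the transcript table gave 12 at day 3 and 17 at day 7 the opposite direction. Over the 14 other settings, the genes called ranged from 7263 to 10384 at day 3, 7596 to 11097 at day 7, 1573 to 4453 between the days and 6634 to 9618 for those called the same way at both times. A 2-fold minimum left 3483, 4124, 496 and 3076 genes, by its construction, and an adjusted p under 0.01 left 963 between the days. Sample weights gave 4453 between the days, and the cause was not tested. Leaving out 1 library gave 7957 to 8871 at day 3, 8694 to 9500 at day 7, 1366 to 2599 between the days and 7214 to 7951 for both times. The lowest between the days were 1366 without day 7 replicate 4 and 1403 without day 7 replicate 1, where fewer samples were compared. Without day 7 replicate 3, the library low in matrix genes, 9123 genes were called at day 7 and 1925 between the days. Without day 3 replicate 1, the library with liver transcripts, 8328 were called at day 3 and 1751 between the days. TPM and the fit without the mitochondrial genome apply the minimum after rescaling and so tested 13984 and 13972 genes.

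The lists called by camera ranged over leave-one-out fits from 23 to 25 at day 3, 28 to 29 at day 7 and 23 to 27 between the days, and over 13 other settings from 23 to 25, 27 to 29 and 21 to 29. With an estimated correlation camera called 0, 0 and 0 lists (8, 6 and 8 at an unadjusted p under 0.05), against 29, 32 and 23 by fry. Lists have no value under the robust fit, since camera has no such option. Of the genes followed, 67 of 68 at day 3, 62 of 62 at day 7 and 53 of 67 between the days kept their direction and side of the threshold throughout. The exception at day 3 was mt-Cytb after quantile normalization (−0.37, adjusted p = 0.106, the highest in a range from 3.24e-09). Against control, median centring and quantile normalization lowered the share of higher calls and TPM raised it. Between the days, median centring moved it from 46.8% to 53.8% and TPM to 56.6%, while it stayed at 46.8% after quantile normalization. With the replicate block, 8880, 9512 and 2336 genes were called. At day 7, where the numbers were treated as pairing the libraries, the block moved no count by 1.5 times and changed no call of a gene or list followed. That fit held all 11 samples, so the day 3 libraries shared its blocks. A paired fit of control and day 7 alone was not run. For day 3 the same-numbered pairs correlated at 0.048, −0.138 and 0.231, and between the days at 0.103, −0.027, 0.338 and −0.03, so the libraries share only a number there. Between the days the block gave adjusted p = 0.0443 for Acta2, which then passed, and 0.0604 for the inflammatory list, which then did not. With the depth unknown, the uncertainty of low values was not measured.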

Other observations

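Transcript shares, stress genes, genes with opposite directions, their values after other scalings and medians without the mitochondrial genome were chosen after their values were seen. The lists were fixed beforehand.

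Collagen processing genes rose with the collagens: 16 of 20 rose and 1 fell at day 3 (median 0.89 relative to all genes, camera adjusted p = 0.0187; adjusted p = 0.68 with an estimated correlation), 18 rose at day 7, 19 when adjusted over the list alone, and 1 fell (1.47, 3e-04; adjusted p = 0.498 with an estimated correlation), and 12 rose and 1 fell between the days, 14 and 1 when adjusted over the list alone (0.88, 3.89e-10; adjusted p = 0.28 with an estimated correlation). The collagen cross-linking enzymes Lox (3.62 at day 3, 5.64 at day 7) and Loxl1 (2.57 and 4.33) were among them. Of 22 endoplasmic reticulum stress genes, 19 rose at day 3 (adjusted p = 0.000234; adjusted p = 0.229 with an estimated correlation) and 18 at day 7, 20 when adjusted over the list alone (0.00331; adjusted p = 0.26 with an estimated correlation), such as Chac1 (3.10 and 2.07), and between the days 5 fell, 9 when adjusted over the list alone and 2 with TPM (0.0598; adjusted p = 0.409 with an estimated correlation). Of 20 YAP and SRF targets, 18 rose at each time (0.000228 and 0.000357; adjusted p = 0.229 and 0.258 with an estimated correlation), such as the receptor kinase Axl (2.66 and 2.62) and Ctgf (2.20 and 2.61). Between the days 4 rose, and 4 rose and 1 fell when adjusted over the list alone, with a median of −0.02, a mean of 0.11 and camera's direction up (0.218; adjusted p = 0.574 with an estimated correlation), and that median is above 0 after each other scaling. Of 18 oxidative stress defence genes, 10 fell and 4 rose at day 3 (0.0135; adjusted p = 0.344 with an estimated correlation) and 11 fell and 4 rose at day 7 (0.00385; adjusted p = 0.26 with an estimated correlation), with glutathione peroxidase 3 (Gpx3) at −2.98 and −4.02 and catalase (Cat) at −1.54 and −2.12. With TPM 6 fell and 7 rose at day 3, and 7 fell and 5 rose at day 7. Between the days 2 fell, 1 when adjusted over the list alone (0.0481; adjusted p = 0.409 with an estimated correlation). Of 13 genes of the insulin-like growth factor axis, 4 rose and 3 fell at day 3 (0.63; adjusted p = 0.87 with an estimated correlation), where the median was −0.15, the mean 0.22, camera's direction down and fry's up, and the median turned to 0.28 with TPM. After median centring 4 rose and 6 fell. At day 7, 7 rose and 2 fell (0.449; adjusted p = 0.779 with an estimated correlation), and 6 rose between the days, 8 when adjusted over the list alone (2.67e-05; adjusted p = 0.207 with an estimated correlation), with Igf1 at 1.41 and Igfbp6 at 2.32.

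Of 22 cholesterol synthesis genes, 5 rose and 6 fell at day 3 (0.154; adjusted p = 0.551 with an estimated correlation), and 3 rose and 8 fell at day 7 (0.0235; adjusted p = 0.26 with an estimated correlation), such as Mvd (−1.75 at day 7), but with TPM the medians of −0.10 and −0.24 turned to 0.28 and 0.17, with 9 rises and 3 falls at day 3 and 6 and 3 at day 7. Between the days 5 fell (0.037; adjusted p = 0.32 with an estimated correlation). Of 26 cytosolic ribosomal proteins, 20 rose at day 3, 22 when adjusted over the list alone, and 5 after median centring (0.0129; adjusted p = 0.68 with an estimated correlation). At day 7, 16 rose, 3 rising and 1 falling after median centring (0.0739; adjusted p = 0.772 with an estimated correlation), and between the days limma called 0, with 0 at an unadjusted p under 0.05 (0.191; adjusted p = 0.782 with an estimated correlation). Of 13 histone genes, 9 rose at each time, with 3 and 4 falls, and 5 rose at day 7 after median centring (0.548 and 0.913; adjusted p = 0.821 and 0.941 with an estimated correlation), and 3 fell between the days (0.0156; adjusted p = 0.343 with an estimated correlation). Among 9 neutrophil markers, 3 rose and 1 fell at day 3, 2 and 1 when adjusted over the list alone, with a median of −0.10 that turned to 0.22 with TPM, a mean of 0.16, camera's direction down and fry's up (0.697; adjusted p = 0.916 with an estimated correlation), 3 rose at day 7 (0.674; adjusted p = 0.898 with an estimated correlation), and 2 rose between the days, Mmp8 by 1.89 and Retnlg by 1.34 (0.00772; adjusted p = 0.417 with an estimated correlation), although the list mean of day 3 replicate 3 (3.279) lay above those of the other day 3 libraries (1.52 to 1.86) and of all day 7 libraries (2.256 to 3.009). Of 9 lymphocyte markers, 4 rose and 5 fell at day 3 (0.0769; adjusted p = 0.551 with an estimated correlation), with Cd4 at 1.47 and the granzyme Gzma at −2.43, but 1 rose and 5 fell after median centring or quantile normalization, 3 rose and 4 fell at day 7 (0.244; adjusted p = 0.663 with an estimated correlation), where the median of 0 was −0.30 after median centring and 0.37 with TPM (4 rises and 3 falls), and 2 rose between the days (0.106; adjusted p = 0.524 with an estimated correlation). Of 6 mesothelium markers, 1 rose and 3 fell at day 3 (0.184; adjusted p = 0.586 with an estimated correlation), 3 rose and 1 fell at day 7 (0.743; adjusted p = 0.887 with an estimated correlation) and 5 rose between the days (0.000271; adjusted p = 0.207 with an estimated correlation), such as Upk1b (1.48). The glia list held 1 tested gene, S100b, which was called at day 7 (1.13) and between the days (1.14) and not at day 3. Camera gave 0.813, 0.579 and 0.0608 for it at day 3, at day 7 and between the days, and adjusted p = 0.87, 0.663 and 0.278 with an estimated correlation. Of 4 adipocyte markers, 2 rose and 1 fell at day 3 (0.618; adjusted p = 0.817 with an estimated correlation), where the median of 0.10 turned to −0.24 after median centring, with 0 rises and 1 fall, and the mean was −0.22 with camera's direction down, and also at day 7, 3 and 1 when adjusted over the list alone (median 0.52, camera's direction down, 0.914; adjusted p = 0.941 with an estimated correlation). Adiponectin (Adipoq) rose by 1.78 between the days (0.254; adjusted p = 0.558 with an estimated correlation). Of 4 sex-linked transcripts, 0 were called by limma at day 3, 1 rose at day 7 and 0 were called between the days, with 0, 1 and 0 at an unadjusted p under 0.05 (0.984, 0.684 and 0.25; adjusted p = 0.995, 0.887 and 0.609 with an estimated correlation), and their median of 0.24 at day 3 turned to −0.09 after median centring.

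The 12 genes called in opposite directions at day 3 and day 7 were Retnla (−1.17 and 2.78), C1qtnf3 (−2.37 and 0.79), Cd55 (−0.75 and 0.57), Wfdc1 (−0.69 and 0.67), Lrrc75b (−0.35 and 0.36) and Fgf11 (−0.27 and 0.26), which were lower and then higher than control, and Agt (0.56 and −0.97), Pigr (0.36 and −0.95), Slc13a1 (0.71 and −0.70), Inpp5b (0.38 and −0.28), Pklr (0.40 and −0.36) and Atp2a3 (0.36 and −0.40), which were higher and then lower. These calls depend on the scaling: 1 of the 12 was called in opposite directions after median centring, 2 after quantile normalization, 5 with TPM and 8 with the mitochondrial genome left out, and only Retnla after each. Of the 990 genes higher at day 7 than at day 3, 63 had been called lower than control at day 3.

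The heat shock genes Hspa1a and Hspa1b, which share reads, were among the most abundant transcripts in every group. Hspa1a stood at 897 ± 67 FPKM in control (rank 25), 1690 ± 181 at day 3 (rank 8) and 2180 ± 170 at day 7 (rank 4). The immediate early genes Fos (226 ± 19.8, 515 ± 92 and 686 ± 67.1 FPKM) and Jun (199 ± 18.1, 428 ± 49.5 and 598 ± 74.8 FPKM) were abundant in control as well.

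With the mitochondrial genome left out and the rest rescaled, day 7 medians relative to all genes were 4.47 for collagens, 2.77 for macrophage and −4.35 for proximal tubule markers. As the pseudocount then weighs less, they do not isolate the effect of the omission. Correlations were at most 0.864 between control and UUO libraries and at least 0.965 within groups.

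In 2395 genes with at least 2 listed transcripts and 10 FPKM in control and at day 7, the most abundant transcript differed between control and day 7 in 248, and in 60 of them the shares of both transcripts did not overlap between the libraries. Shares without overlap were found for 22.5% of 8017 transcripts, against 5.71% by chance. The share of 1 transcript went from 0.909% ± 1.57 to 72.8% ± 25.7 in Pmp22, from 17.9% ± 3.82 to 70.4% ± 3.58 in Cndp2 and from 7.96% ± 1.01 to 59.5% ± 11.1 in Snx5 (SD, n = 3 and 4). These are shares of estimated transcript FPKM, and a change of cell type mixture was not separated from a change within cells.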
